A study of Mus musculus with 4 samples.

How the data were processed

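Intestinal crypts of C57BL/6 mice were profiled cell by cell in 4 samples, 2 from mice on a control diet and 2 from mice on a diet rich in arachidonic acid (AA), each kept on its diet for 4 months, per the labels' protocols. Cells that excluded DAPI, a dye that enters dead cells, were sorted and loaded for droplet-based 3' RNA sequencing with unique molecular identifiers (UMIs), aiming at 8000 cells per sample, per the labels' protocols. Most labels call the material crypts, while the extraction protocol in the same labels speaks of organoids. Immune cells made up part of every sample. The labels do not say how many mice a sample holds or what equal replicate numbers share, so the p-values measure only the spread between these samples, which may be technical.

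The deposited matrices hold raw UMI counts, whole numbers per gene and cell barcode with no normalization, 1 matrix per sample. They were made with Cell Ranger 4.0.0 on mouse genome build mm10, per the submitters' processing notes. The annotation release, the alignment settings and any removal of doublets are not stated. Each matrix lists 32285 genes. Coordinates were taken by gene identifier from a GENCODE annotation of the same genome assembly, where 32235 of these identifiers were found. The files held 9186 and 7145 barcodes for control replicates 1 and 2, and 6568 and 11262 for AA-rich replicates 1 and 2. 

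Barcodes were kept with at least 500 detected genes, at least 1000 UMIs and under 20% of UMIs from mitochondrial genes. Doublets were scored with Scrublet as built into scanpy 1.11.5 (Python 3.11.15). Its automatic limit marked 0.0129% of the cells of control replicate 1 and 0% of those of AA-rich replicate 2. The highest-scoring share expected from the loading was therefore removed in each sample, 0.8% per 1000 barcodes, a rule chosen after those counts were seen. It removed 508 and 338 cells from control replicates 1 and 2 and 288 and 765 from AA-rich replicates 1 and 2. This left 7261, 5669, 5212 and 8511 cells, 26653 in all, with a median of 5636, 9536, 9242 and 6043 UMIs per cell. Thus a cell of control replicate 2 or AA-rich replicate 1 was read more deeply than one of the other samples, and the order of depth did not follow the diet.

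Cells were clustered on log-normalised counts of 2000 variable genes chosen across samples, 30 principal components and 15 neighbours, with the Leiden method (python-igraph 0.11.9) at resolution 1.0, which gave 24 clusters. No batch correction was applied. A cluster took the name of the marker class with the highest mean log2 ratio of its CPM to that of all other cells, with 10 CPM added to each. It needed a score of at least 0.5 and, for the epithelial classes, at least 3 markers raised by over 0.5. The 123 markers of 16 classes were fixed before the data were examined, and the scoring rule was set afterwards. Clusters that scored highest for colonocyte markers stayed unnamed, because genes of small intestinal absorptive cells led them. Clusters with low UMI counts and none of the named class's markers among their leading 10 genes stayed unnamed and outside the epithelium. The names rest on these markers alone, and no other cell annotation was used here. Of the 24 clusters, 17 were epithelial-like and 5 of these had no class name. The unnamed epithelial-like cells entered the sum over all epithelial-like cells and made up 36.4, 27.6, 29.8 and 28.6% of the epithelial-like cells of control replicates 1 and 2 and AA-rich replicates 1 and 2.

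Cells are not replicates, so UMI counts were summed per sample over all epithelial-like cells and over each class, and the 4 sums were compared between the diets. A class was tested where every sample held at least 30 of its cells. Paneth-like cells were left untested, with 23 cells in AA-rich replicate 1. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3), using its quasi-likelihood test and the Benjamini-Hochberg adjustment, with an adjusted p under 0.05 counted as changed. Standard errors are the log2 fold change divided by the square root of the F statistic. Whether the diet effect differed between stem-like and enterocyte-like cells was tested as an interaction, with the sample as a block. Shares of cell classes among epithelial-like cells were compared with an exact two-sided permutation test of the 4 sample shares, which cannot give a p below 0.33.

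The 20 gene lists (Lgr5 stem cell genes, Wnt targets, fetal-like and regenerative genes, YAP targets, eicosanoid synthesis and breakdown, prostaglandin receptors with cAMP-CREB targets, fatty acid synthesis and desaturation, cholesterol synthesis, PPAR targets with fatty acid oxidation, interferon-stimulated genes, MHC class II presentation, cell cycle, immediate early and heat shock genes, NRF2 and glutathione genes, antimicrobial genes, Notch and secretory regulators, unfolded protein response, enterocyte nutrient uptake, ketogenesis and stem cell metabolism, mitochondrially encoded genes) were tested with camera on voom values in limma 3.58.1, with a preset correlation between genes of 0.01. The same lists were tested with an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance. A further list of sex-linked genes was only described. Lists of proximal and distal intestinal genes were added after the first results were seen.

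Genes were named by a rule. Where genes passed with both AA-rich samples on the same side of both controls, the 10 highest and 10 lowest fold changes at a mean of at least 10 CPM were named for the main populations, and 5 and 5 for the smaller classes. Where none passed, the 5 with the smallest p at that level were named as not passing. Up to 4 members of each list with a called change were named, smallest p first, and 14 genes were always given where tested (Lgr5, Ascl2, Olfm4, Ly6a, Clu, Tacstd2, Ptgs2, Ptger4, Fads1, Fads2, Hmgcs2, Pdk4, Scd1, Mki67). Genes named outside this rule are said to be so where they appear. The markers, the 20 gene lists, the main tests, the naming rule for genes and the choices to be varied were set before the data were examined, except those said here or beside their results to have been added or chosen later.

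The tests were tried on simulated data, drawn from the real means and library sizes with 100 genes changed by 1 and 100 by 2 on the log2 scale. With edgeR, 93 of the smaller changes were recovered in all epithelial-like cells (35 false among 228 calls), 95 in stem-like cells (6 of 201), 97 in cycling cells (12 of 209), 73 in enterocyte-like cells (14 of 187), 97 in goblet-like cells (16 of 213), 73 in enteroendocrine-like cells (15 of 188) and 26 in tuft-like cells (2 of 122). All 100 of the larger changes were recovered in each of these except tuft-like cells, with 94 of 99. The interaction test recovered 48 and 98 of 100, with 12 false among 158 calls. Lists of 25 genes raised by 0.5 were called by camera in 20 of 20 draws in all epithelial-like, stem-like and enterocyte-like cells, and unchanged lists in 0, 2 and 1 of 20. Each gene was drawn independently, so these lists held no correlation between genes. The draws therefore cannot show how often camera's preset correlation gives false calls in real lists. For single genes they also lacked deviations shared by genes of a sample, and many genes were changed at once, which eases the adjusted threshold. The shares recovered may thus be higher than in the real data.

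The analysis was repeated with DESeq2 1.42.0 in place of edgeR, RLE scaling, no filter on low counts, the replicate number as a block, leaving out each sample in turn, a mitochondrial limit of 10%, every deposited barcode, doublets kept, a Leiden resolution of 0.5, thinning to the lowest mean depth per cell, the estimated correlation and fry, and edgeR on cell numbers for the shares. Fits within single stem-like or enterocyte-like clusters were added after the clusters were seen. Plots were drawn with matplotlib 3.10.9.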

Results

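Intestinal crypts hold the stem cells that renew the gut lining. Single crypt cells of C57BL/6 mice were profiled by RNA sequencing after 4 months on a control diet (2 samples) or on a diet rich in arachidonic acid (2 samples), the fatty acid from which prostaglandins and other eicosanoids are made. The title of the series gives the question, whether dietary arachidonic acid (AA) alters intestinal stemness. After filtering, 26653 cells remained, 7261 and 5669 in control replicates 1 and 2 and 5212 and 8511 in AA-rich replicates 1 and 2, at a median of 5636, 9536, 9242 and 6043 UMIs per cell. Epithelial-like cells made up 87.2, 85.3, 73.7 and 91.4% of these cells, in the same order. T or NK-like cells were the main other class, at 10.6, 12.4, 23.0 and 5.98%. Values below are given in this order of samples unless stated otherwise, and levels are in CPM, the UMI counts of the summed cells scaled to the same total.

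Cycling cells, which express Mki67, Top2a and other genes of DNA replication and mitosis, made up 13.5% ± 1.25 of epithelial-like cells on the control diet and 18.9% ± 1.18 on the AA-rich diet (mean ± SD, n = 2 samples each). The share was 12.6 and 14.4% in the controls and 18.0 and 19.7% in the AA-rich samples, so both AA-rich samples lay above both controls. Stem-like cells took 24.2 and 12.4% on the control diet and 23.2 and 17.6% on the AA-rich diet. They came from a cluster led by Gkn3, Olfm4 and Lgr5 and from another led by Olfm4 and Myc, with replication genes such as Mcm2 and Cdt1 among its top genes, which held 42.4, 42.4, 36.9 and 52.0% of the class. Enterocyte-like cells, the absorptive cells, took 11 and 29.2% against 12 and 17.5%. Goblet-like cells, which secrete mucus, took 9.17 and 8.83% against 9.32 and 9.53%, and Paneth-like cells, which secrete antimicrobial peptides, 0.506 and 0.682% against 0.599 and 1.30%. Hormone-secreting enteroendocrine-like cells took 3.70 and 4.05% against 3.65 and 3.46%, and chemosensory tuft-like cells 2.48 and 2.77% against 3.41 and 2.33%. The exact permutation test gave p = 0.33 for cycling, goblet-like and enteroendocrine-like cells, the smallest that 2 against 2 samples allow. The same exact test gave p = 0.67 for Paneth-like cells and p = 1 for stem-like, enterocyte-like and tuft-like cells, so no share difference could be told from chance. edgeR's quasi-likelihood test on cell numbers gave the cycling share a log2 fold change of 0.49, with p = 0.034 before and 0.239 after adjustment over the 7 classes.

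The mean share of stem-like cells was 2.11 percentage points higher on the AA-rich diet, and 3.76 points lower without control replicate 2 and 0.66 lower without AA-rich replicate 1. For enterocyte-like cells the mean was 5.40 points lower, and 3.72 points higher without control replicate 2. Tuft-like cells went from 0.24 points higher to 0.30 lower without AA-rich replicate 1. The Paneth-like difference of 0.35 points came to 0.70 without AA-rich replicate 1 and to 0.0051 without AA-rich replicate 2, and it was 0.19 points lower with every deposited barcode.

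**Figure D1:**
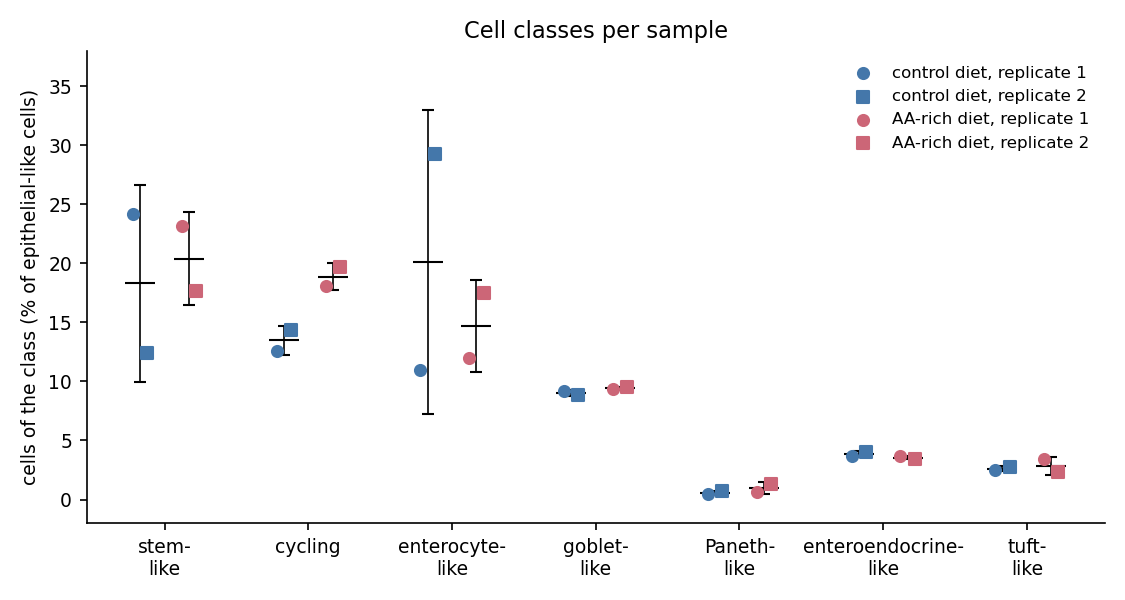
Share of each cell class among epithelial-like cells, in percent, with 1 point per sample (2 control diet, 2 AA-rich diet), a line at each group's mean and bars of 1 SD. Cycling cells lie at 12.6 and 14.4% in the controls and at 18.0 and 19.7% in the AA-rich samples, while stem-like and enterocyte-like shares overlap between the diets.

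In stem-like cells, the class the study is about, Lgr5, the receptor that marks crypt base stem cells (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780, minus strand, mm10), stood at 135 and 137 CPM in the controls and 118 and 140 in the AA-rich samples. Its log2 fold change was -0.08 ± 0.12 (SE, n = 2 samples per diet). Ascl2, a transcription factor of these cells, had -0.03 ± 0.16, and Olfm4 (ENSMUSG00000022026, chromosome 14, 79984081 to 80023139, plus strand) had -0.10 ± 0.17. The desaturase genes that act in AA synthesis had 0.00105 (Fads1) and -0.02 ± 0.10 (Fads2), and the prostaglandin E2 receptor gene Ptger4 had 0.20 ± 0.21. Clu, a gene of regenerating crypts, had -0.07 ± 0.37, Hmgcs2, the rate-limiting enzyme of ketogenesis, 0.21 ± 0.16, Pdk4 0.95 ± 0.65 and Mki67 0.14 ± 0.12. Ly6a, Tacstd2, Ptgs2 and Scd1 were too low to be tested. None of these differences exceeded the spread between samples (edgeR, adjusted p = 1.00 for each). Several of these small values changed sign with 1 sample left out, among them Lgr5 to 0.04 and Ascl2 to 0.20 without AA-rich replicate 1.

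All 7 measured genes of MHC class II antigen presentation were lower in stem-like cells of the AA-rich diet, by a median of -0.59 on the log2 scale. Cd74, the invariant chain (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652, plus strand), stood at 37.7 and 53.4 CPM in the controls and at 23.7 and 30.5 in the AA-rich samples (-0.74 ± 0.18). Ciita, the master regulator of these genes, had -1.09 ± 0.44, H2-DMa -0.57 ± 0.18 and H2-Eb1 -0.64 ± 0.31. Of the 7, 4 had both AA-rich samples below both controls, where chance separates the diets one way or the other in a share of 0.333. The list fell in camera (adjusted p = 6.73e-05), but not with an estimated correlation (adjusted p = 0.816 with an estimated correlation). Adjusted over the list alone, 2 members passed in edgeR, Cd74 (0.0199) and H2-DMa (0.0409), and 0 passed over all genes. Without control replicate 2 the list's median was -0.25. In cycling cells the list was not lower, with 4 of 6 members higher (median 0.09), while 4 of 5 were lower in enteroendocrine-like cells (median -0.33). Myeloid cells, whose cluster had Cd74 and H2-Eb1 among its top genes, were also fewer in both AA-rich samples. They made up 0.303, 0.388, 0.153 and 0.211% of kept cells.

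Immediate early and heat shock genes were lower in 14 of 19 (median -0.17), led by the immediate early transcription factors. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273, plus strand) stood at 39.1 and 26.3 CPM against 12.7 and 17.1 (-1.16 ± 0.21), Fosb had -1.99 ± 0.49 and Egr1 -0.80 ± 0.28. The heat shock gene Dnaja1 went the other way, at 0.40 ± 0.15. The list fell in camera (adjusted p = 0.0151, and adjusted p = 0.816 with an estimated correlation), and Fos (0.00639) and Fosb (0.0240) passed adjusted over the list alone, against 0 over all genes. That call was lost without control replicate 1 (adjusted p = 0.119), AA-rich replicate 1 (0.0811) or AA-rich replicate 2 (0.122). Cell cycle genes were higher in 22 of 30 (median 0.13), among them Ccnb1 (0.45 ± 0.15), Tpx2 (0.62 ± 0.22), Birc5 (0.27 ± 0.13) and Cdc20 (0.23 ± 0.11). This list rose in camera (adjusted p = 0.0015, and adjusted p = 0.816 with an estimated correlation) with 0 members passing adjusted over the list alone or over all genes. It lost its call without control replicate 1 (0.466) or AA-rich replicate 2 (0.47).

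The Lgr5 stem cell list itself had 9 genes higher and 13 lower in stem-like cells, with a median of -0.07 (camera adjusted p = 0.293). The other 16 lists had adjusted p from 0.0639 (YAP targets, 5 of 6 lower, median -0.19) to 0.929, including Wnt targets (12 of 15 lower, median -0.10, 0.13), fetal-like and regenerative genes (8 of 13 lower, 0.734), and eicosanoid synthesis and breakdown (9 of 17 higher, 0.709). Over all 11474 genes tested in stem-like cells, edgeR called 0 changed, DESeq2 0, and 492 had an unadjusted p under 0.05. The 5 genes with the smallest p, none of which passed (adjusted p = 1.00), were Fos, Selenop (-0.79 ± 0.15), Naaladl1 (-0.87 ± 0.18), Bex1 (-0.75 ± 0.16) and Banp (1.27 ± 0.27). The count rested on the samples used, with 249 genes called without AA-rich replicate 1, 8 without AA-rich replicate 2, 6 without control replicate 2 and 0 without control replicate 1. With the replicate number as a block, whose meaning no label gives, edgeR called 134 genes in stem-like cells, the 5 named above among them. Distal intestine genes, a list chosen after results were seen, were lower in stem-like cells in 7 of 8 (median -0.82, camera p = 8.55e-07, and p = 0.0542 with an estimated correlation).

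Over all epithelial-like cells, every one of 30 cell cycle genes was higher on the AA-rich diet (median 0.26), among them Aurka (0.43 ± 0.12), Hells (0.46 ± 0.13), Ccnb1 (0.29 ± 0.10) and Cenpf (0.38 ± 0.13). In 24 of them both AA-rich samples lay above both controls, where chance gives a separation either way in a share of 0.333. All 25 genes of cholesterol synthesis were lower (median -0.27), 13 of them separated, with Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, plus strand) at 137 and 130 CPM in the controls and 112 and 85.6 in the AA-rich samples. Msmo1 had -0.47 ± 0.16, Sc5d -0.27 ± 0.10 and Dhcr7 -0.29 ± 0.11. In camera the first list rose (adjusted p = 5.41e-14) and the other fell (1.56e-10), while adjusted p = 0.243 and adjusted p = 0.967 with an estimated correlation. Fry gave adjusted p = 0.0507 and 0.997, and 0 members of either list passed adjusted over the list alone or over all genes. Without AA-rich replicate 2 the cholesterol median was -0.12 (adjusted p = 0.00286). The rise of the cell cycle list went with the larger share of cycling cells in both AA-rich samples. Within cycling cells, in a test chosen after results were seen, 22 of 30 were lower (median -0.06, camera adjusted p = 0.0543). They were higher in 22 of 30 in goblet-like, 23 of 30 in enteroendocrine-like and 25 of 29 in tuft-like cells (camera adjusted p = 0.253, 0.0605 and 3.19e-05). With an estimated correlation these 4 classes had adjusted p = 0.445, 0.916, 0.843 and 0.999.

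Lgr5 stem cell genes were higher in 21 of 22 (median 0.20), among them Tnfrsf19 (0.50 ± 0.18), Cdca7 (0.37 ± 0.15), Soat1 (0.38 ± 0.17) and Cdk6 (0.26 ± 0.12), and Wnt targets in 14 of 16 (median 0.13), among them Cd44 (0.40 ± 0.14), Ccnd1 (0.25 ± 0.11), Lgr5 (0.32 ± 0.15) and Ephb2 (0.18 ± 0.10). Both lists hold Lgr5, Ascl2, Axin2, Rnf43, Znrf3, Sp5 and Sox9, so their rises are not independent. Enterocyte nutrient uptake genes were lower in 21 of 22 (median -0.46), among them the brush border enzymes Alpi (-0.43 ± 0.18) and Sis (-0.56 ± 0.27), Scarb1 (-0.50 ± 0.25) and the glucose transporter gene Slc2a2 (-0.63 ± 0.32). NRF2 and glutathione genes were lower in 16 of 19 (median -0.13; Nqo1 -0.25 ± 0.11, Gsta4 -0.46 ± 0.21, Ugdh -0.30 ± 0.17, Gsta2 -0.97 ± 0.58). MHC class II genes were lower in 6 of 7 (median -0.13), with Ciita at -0.70 ± 0.25, H2-DMa at -0.29 ± 0.13, Cd74 at -0.19 ± 0.17 and H2-Ab1 at -0.13 ± 0.21. These lists passed in camera (adjusted p = 9.49e-06, 0.00364, 0.00131, 0.0201 and 0.0456), with adjusted p = 0.967 with an estimated correlation for each and 0 members passing adjusted over the list alone or over all genes. Control replicate 2, with the largest enterocyte-like share, carried the first 4. Without it the stem cell, Wnt and NRF2 lists did not pass (adjusted p = 0.963, 0.713 and 0.963), and the uptake list was higher instead (median 0.20, 0.0351). Without AA-rich replicate 1 the Wnt, uptake, NRF2 and MHC class II lists did not pass (0.103, 0.654, 0.158 and 0.654), and the MHC class II list did not pass without control replicate 1 (0.164) or control replicate 2 (0.12) either. The other 13 lists had adjusted p from 0.463 to 0.955.

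Among the genes always given, Lgr5 had 0.32 ± 0.15, Hmgcs2 0.49 ± 0.17, Ascl2 0.22 ± 0.19, Olfm4 0.21 ± 0.26 and Mki67 0.25 ± 0.14. Scd1, Pdk4, Clu, Fads1, Ly6a, Ptger4 and Fads2 lay between 0.60 (Scd1) and 0.01 (Fads2). Of 14380 genes tested, edgeR called 0 changed, with 566 at an unadjusted p under 0.05, and DESeq2 called 5. The smallest p belonged to Gcg, the proglucagon gene of enteroendocrine cells (ENSMUSG00000000394, chromosome 2, 62474530 to 62483650, minus strand), at 63.8 and 89.2 CPM against 35.2 and 36.7 (-1.09 ± 0.17). It was followed by the lipase gene Pnliprp2 (0.96 ± 0.17), the serine synthesis gene Phgdh (0.61 ± 0.13), the Paneth cell metalloprotease gene Mmp7 (0.67 ± 0.14) and the tubulin gene Tuba1c (0.56 ± 0.12), all with an adjusted p of 0.955 in edgeR. Gcg (adjusted p = 0.00052) and Pnliprp2 (0.0328) passed in DESeq2. The count was 50 without AA-rich replicate 1 and 1 without control replicate 2.

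In enterocyte-like cells of the AA-rich diet, 25 of 28 PPAR targets and genes of fatty acid oxidation were higher (median 0.30), 19 of them in both AA-rich samples over both controls, where chance separates the diets either way in a share of 0.333. Hmgcs2 (ENSMUSG00000027875, chromosome 3, 98280435 to 98310738, plus strand) stood at 28.1 and 19.8 CPM in the controls and at 48.7 and 60.7 in the AA-rich samples (1.23 ± 0.21). Angptl4, an inhibitor of lipoprotein lipase, had 1.53 ± 0.29, the acyl-CoA thioesterase gene Acot1 1.75 ± 0.29 and the fatty acid hydroxylase gene Cyp4a10 1.46 ± 0.31. Acot1 and Cyp4a10 have close paralogs, so how their reads were assigned is uncertain. The list rose in camera (adjusted p = 4.66e-18), but adjusted p = 0.69 with an estimated correlation. These 4 genes and Pdk4 passed adjusted over the list alone (Hmgcs2 0.00552, Angptl4 0.00767, Acot1 0.00552, Cyp4a10 0.0128), against 0 over all genes.

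All 25 genes of cholesterol synthesis were lower in enterocyte-like cells (median -0.54), 10 of them separated. The rate-limiting enzyme gene Hmgcr stood at 57.5 and 47.9 CPM against 41.8 and 30 (-0.56 ± 0.19), the low-density lipoprotein receptor gene Ldlr had -0.61 ± 0.23, Dhcr24 -0.46 ± 0.17 and Mvk -0.77 ± 0.31. The list fell in camera (adjusted p = 6.61e-19, and adjusted p = 0.69 with an estimated correlation), with 0 members passing adjusted over the list alone or over all genes. Most of that difference came from AA-rich replicate 2, and without it the median was -0.13 and the call was lost (adjusted p = 0.0508). The 25 levels summed to 1549 and 1311 CPM in the controls and to 1310 and 802 in AA-rich replicates 1 and 2. Without AA-rich replicate 1 the median was -0.97 (8.97e-30).

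**Figure D2:**
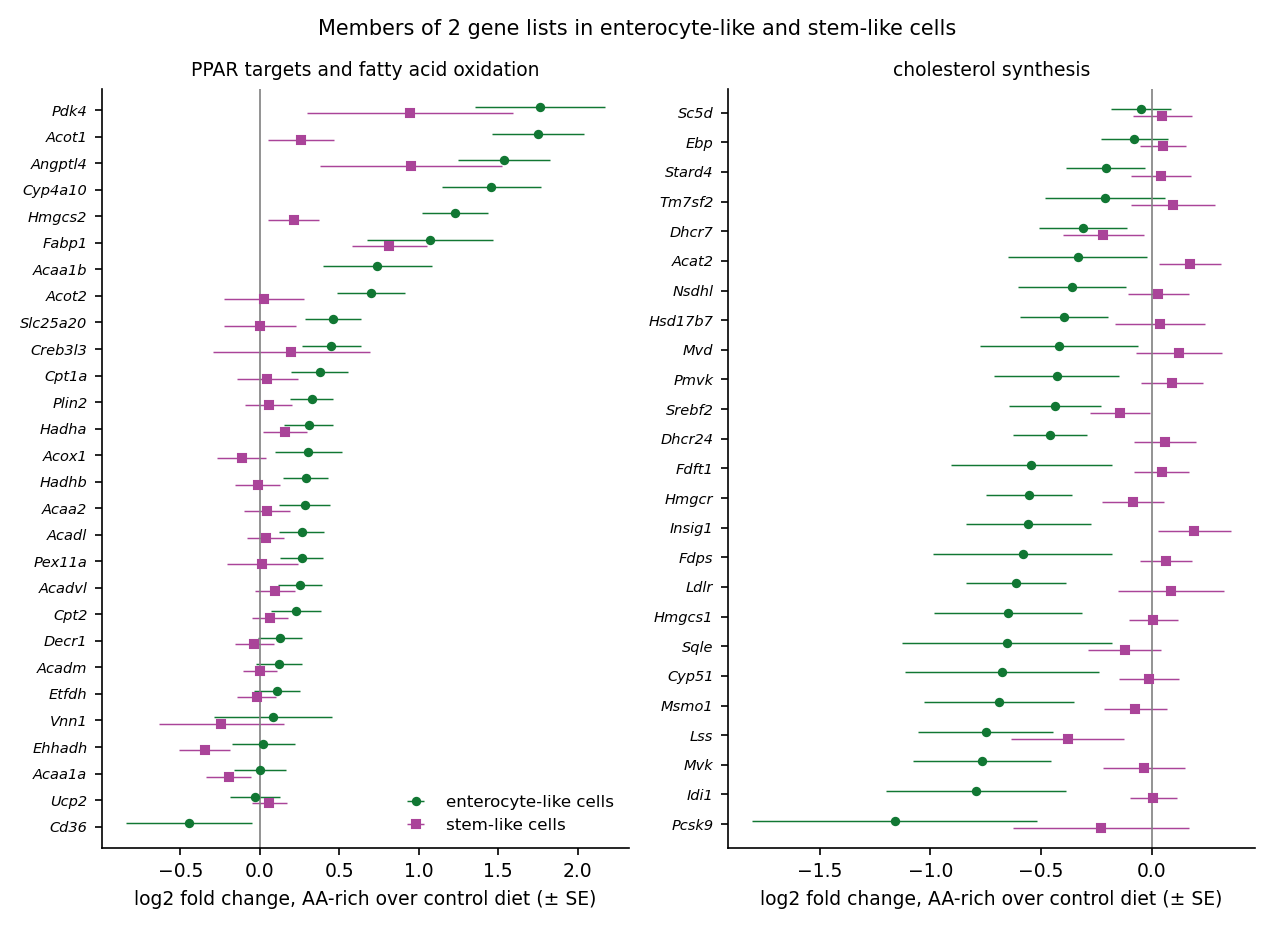
Log2 fold change, AA-rich over control diet, of each member of the PPAR target and cholesterol synthesis lists in enterocyte-like cells (circles) and stem-like cells (squares), with bars of 1 SE. In enterocyte-like cells the medians lie at 0.30 and -0.54, and in stem-like cells at 0.05 and 0.04.

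The ketogenesis and stem cell metabolism list was higher in 7 of 12 (median 0.05, adjusted p = 0.0256), with Hmgcs2 (0.00473) and Pdk4 (1.76 ± 0.41, 0.0163) passing adjusted over the list alone, Cpt1a at 0.38 ± 0.18 and Ppara at 0.30 ± 0.15. Immediate early and heat shock genes were higher in 17 of 21 (median 0.33, 0.000367), with Dusp1 at 0.99 ± 0.48, Klf6 at 0.27 ± 0.14 and Klf4 at -0.38 ± 0.18. Hspa1a was highest in AA-rich replicate 1 and next highest in control replicate 1, at 12.6, 0.464, 93.0 and 0.353 CPM. An unnamed epithelial-like cluster led by Hspa1a, Hspa1b and Jun was also largest in that sample, at 1.19, 0.889, 3.41 and 0.206% of epithelial-like cells. Prostaglandin receptor and cAMP-CREB target genes were higher in 10 of 11 (median 0.19, 0.021; Areg 0.75 ± 0.35, Per1 0.68 ± 0.77, Ppargc1a 0.12 ± 0.16), fetal-like and regenerative genes in 12 of 16 (median 0.18, 0.0256; Krt7 0.59 ± 0.17, Ly6a 1.00 ± 0.42, Itga2 -0.34 ± 0.23) and cell cycle genes in 14 of 23 (median 0.06, 0.0256; Rrm1 0.54 ± 0.26, Hells 1.05 ± 0.61, Aurkb 1.04 ± 0.71, Aurka 0.61 ± 0.54). With an estimated correlation these 5 lists had adjusted p = 0.766, 0.766, 0.69, 0.69 and 0.766. Outside ketogenesis, 0 of their members passed adjusted over the list alone. The 1 lower member of the prostaglandin receptor and cAMP-CREB target list was the receptor gene Ptger4 (-0.03 ± 0.39). That list shares Fos and Dusp1 with the immediate early list and Areg with the fetal-like list. The ketogenesis list shares Hmgcs2, Pdk4 and Cpt1a with the PPAR target list, so these calls are not independent. In the same enterocyte-like cells all 8 measured T or NK cell markers were higher (median 1.31, sums 28.1, 9.54, 27.4 and 61.3 CPM, 2 passing adjusted over the list alone and 0 over all genes), as were both measured myeloid markers, and Ly6a, which lymphocytes also express, stood at 1.20, 1.26, 2.37 and 2.59 CPM.

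None of these 5 calls held with each sample left out. The ketogenesis, immediate early, fetal-like, and prostaglandin receptor with cAMP-CREB target lists did not pass without AA-rich replicate 1, nor without control replicate 2. The fetal-like list did not pass without control replicate 1 or AA-rich replicate 2 either, nor the cell cycle list without AA-rich replicate 2. Cell cycle genes were lower instead without control replicate 2 (median -0.35) and with a mitochondrial limit of 10% (median -0.27, camera adjusted p = 4.74e-06). The other 13 lists had adjusted p from 0.0799 (unfolded protein response) to 0.696. Of 10374 genes, edgeR called 0 changed, with 247 at an unadjusted p under 0.05, and DESeq2 called 1. The smallest p belonged to Me1, the NADPH-making malic enzyme (ENSMUSG00000032418, chromosome 9, 86581371 to 86695953, minus strand), at 10.0 and 9.15 CPM against 21.9 and 34.5 (1.58 ± 0.25), then Hmgcs2, Angptl4, the calcium-binding S100g (0.99 ± 0.19) and Gsdmc4 (1.05 ± 0.22), none passing in edgeR (adjusted p = 1.00), while Me1 passed in DESeq2 (1.57, adjusted p = 0.0234). Without AA-rich replicate 1, 66 were called. The cluster led by Apoa1 and Lct held 18.1, 51.6, 23.3 and 65.3% of the enterocyte-like cells, so the class was made up differently in replicates 1 and 2 of both diets.

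In cycling cells the histone gene Hist1h2ap (ENSMUSG00000094777, chromosome 13, 21833026 to 21833507, minus strand) stood at 65.0 and 62.4 CPM in the controls and at 34.2 and 37.5 in the AA-rich samples (-0.83 ± 0.11). It did not pass in edgeR (adjusted p = 0.251) but did in DESeq2 (0.0316), and as a member of a histone gene family its reads may be shared with near copies. The Notch target Nrarp (-0.55 ± 0.11), S100g (0.86 ± 0.17), Selenop (-0.76 ± 0.15) and the antimicrobial lectin gene Reg3g (-0.88 ± 0.18) came next (adjusted p = 0.965). Of 11551 genes, edgeR called 0, with 594 at an unadjusted p under 0.05, and DESeq2 called 1. The count was 375 without AA-rich replicate 1 and 40 without AA-rich replicate 2.

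In goblet-like cells Ang4, an antimicrobial ribonuclease gene (ENSMUSG00000060615, chromosome 14, 51763878 to 51773590, minus strand), stood at 47.3 and 62.5 CPM against 111 and 97.1 (0.92 ± 0.16). Rgs2 (-0.68 ± 0.13), Banp (1.09 ± 0.22), Eif3j1 (0.75 ± 0.16) and S100a14 (-0.71 ± 0.16) followed, and none passed in edgeR (adjusted p = 0.999). Of 11460 genes, edgeR called 0, with 408 at an unadjusted p under 0.05, and DESeq2 called 1. Without control replicate 1 the count was 1, without control replicate 2 it was 12, and without AA-rich replicates 1 and 2 it was 366 and 69.

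Defa24, an antimicrobial alpha-defensin gene of Paneth cells (ENSMUSG00000064213, chromosome 8, 21734494 to 21735471, plus strand), was the gene called in enteroendocrine-like and in tuft-like cells. It stood at 55.2 and 46.5 CPM in the controls and at 199 and 337 in the AA-rich samples in enteroendocrine-like cells (2.40 ± 0.24, edgeR adjusted p = 0.00241). In tuft-like cells it stood at 10.9 and 15.5 against 155 and 91.9 (3.21 ± 0.32, edgeR adjusted p = 0.0162). The alpha-defensins form a family of near-identical genes, so how reads were assigned to Defa24 is uncertain. A few cells held much of the RNA. In tuft-like cells of AA-rich replicate 1, the richest 2 of 131 cells held 241 and 66 of 364 Defa24 UMIs, and without the 5 richest cells of each sample the levels were 7.17, 6.92, 8.10 and 46.9 CPM. In enteroendocrine-like cells they were 20.9, 16.4, 38.3 and 148 CPM without the 5 richest cells, with both AA-rich samples still above both controls. The share of cells with a Defa24 UMI was 8.28, 11.9, 13.0 and 26.0% in tuft-like and 14.1, 14.8, 22.1 and 40.5% in enteroendocrine-like cells. It was 2.85, 2.85, 4.01 and 14.7% in T or NK-like cells, which do not make defensins, at a median of 1271, 1616.5, 1634 and 1239 UMIs per cell against 4807, 8515, 10975 and 4325 in tuft-like cells and 6542, 12995.5, 22900.5 and 9437 in enteroendocrine-like cells.

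**Figure D3:**
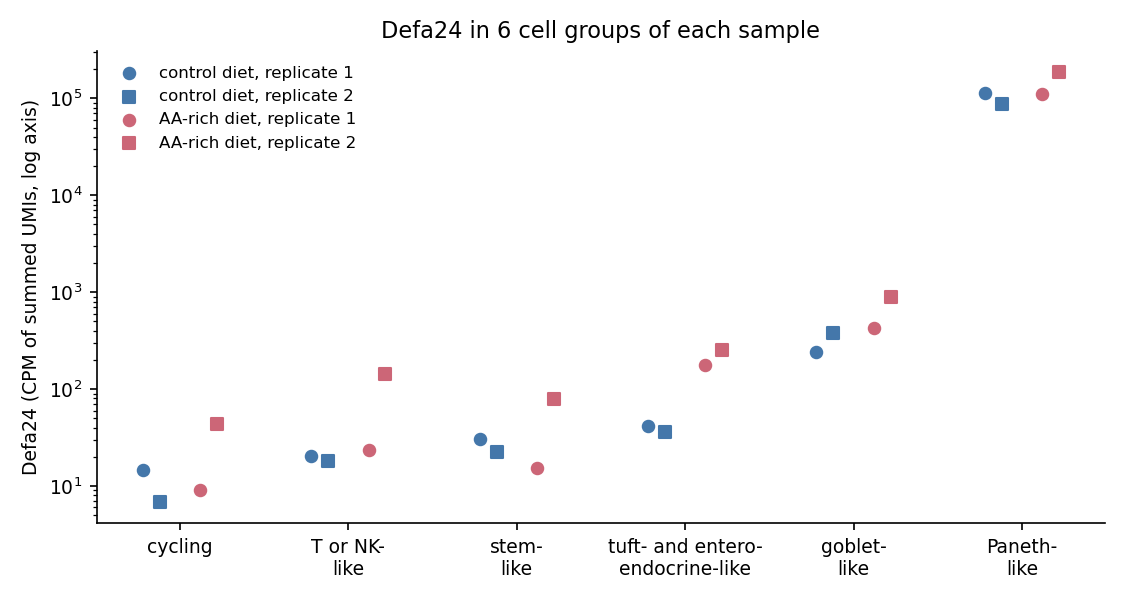
Defa24 level in CPM on a log axis, in 6 cell groups, with 1 point per sample. Tuft-like and enteroendocrine-like cells together lie at 41.7 and 36.1 CPM in the controls and at 178 and 256 in the AA-rich samples, and Paneth-like cells lie far above all other groups.

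The tuft-like call was lost without control replicate 1 (3.01, adjusted p = 0.222) or control replicate 2 (3.51, 0.063), and the enteroendocrine-like call with a mitochondrial limit of 10% (1.93, 0.885), all from edgeR. Of 11033 genes in enteroendocrine-like cells edgeR called 1, with 552 at an unadjusted p under 0.05, and DESeq2 called 2. Leaving out control replicates 1 and 2 gave 34 and 17, and leaving out AA-rich replicates 1 and 2 gave 264 and 76. Of 9480 genes in tuft-like cells edgeR called 1, with 255 at an unadjusted p under 0.05, and DESeq2 called 2. Leaving out either control gave 0, and leaving out AA-rich replicates 1 and 2 gave 295 and 43.

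Lgr5 had 0.51 ± 0.14 in cycling, 0.40 ± 0.18 in goblet-like, 0.65 ± 0.19 in enteroendocrine-like and 0.06 ± 0.20 in tuft-like cells (n = 2 samples per diet). None passed in edgeR (adjusted p = 0.965, 0.999, 0.919 and 0.999), and the cycling value passed without AA-rich replicate 1 (0.70, edgeR adjusted p = 0.000342) and without a filter on low counts (0.52, 0.0086). Of the 2 clusters of cycling cells, that led by Top2a, Hist1h1b and Cenpf held 45.2 and 43.0% of the class in the controls and 54.3 and 49.5% in the AA-rich samples. The other genes always given did not pass in these classes either. In cycling cells Clu had 1.36 ± 0.47 at a mean of 1.08 CPM, Hmgcs2 0.38 ± 0.13, Pdk4 0.32 ± 0.83, Olfm4 0.20 ± 0.15, Ascl2 0.07 ± 0.14, Fads1 0.03 ± 0.11, Ly6a -0.02 ± 0.45, Ptger4 -0.02 ± 0.16, Fads2 -0.03 ± 0.10 and Mki67 -0.09 ± 0.14. In goblet-like cells Hmgcs2 had 0.59 ± 0.17, Ly6a 0.50 ± 0.31, Pdk4 0.27 ± 0.70, Olfm4 0.25 ± 0.21, Mki67 0.18 ± 0.18, Ascl2 0.11 ± 0.24, Fads2 0.03 ± 0.12, Fads1 0.02 ± 0.14 and Ptger4 -0.03 ± 0.18. In enteroendocrine-like cells Ascl2 had 0.55 ± 0.20, Hmgcs2 0.49 ± 0.17, Olfm4 0.44 ± 0.21, Ptger4 0.35 ± 0.27, Mki67 0.24 ± 0.20, Fads1 0.20 ± 0.17, Fads2 0.11 ± 0.15 and Pdk4 -0.54 ± 0.36. In tuft-like cells Hmgcs2 had 0.41 ± 0.30, Olfm4 0.14 ± 0.24, Mki67 0.12 ± 0.27, Fads2 -0.04 ± 0.23, Ptger4 -0.05 ± 0.64, Ascl2 -0.23 ± 0.23 and Fads1 -0.33 ± 0.26. In enterocyte-like cells Mki67 had 0.30 ± 0.36, Olfm4 0.14 ± 0.44, Fads2 0.02 ± 0.29, Ptger4 -0.03 ± 0.39 and Fads1 -0.14 ± 0.49. Without AA-rich replicate 2, Hmgcs2 passed in edgeR in cycling (0.53, 0.0388) and goblet-like cells (0.71, 0.00182), and Olfm4 in enteroendocrine-like cells (0.55, 0.0107).

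The diet effect in stem-like cells was set against that in enterocyte-like cells of the same samples. Hmgcs2 had 0.21 ± 0.16 in stem-like and 1.23 ± 0.21 in enterocyte-like cells (n = 2 samples per diet), a difference of -1.01 ± 0.24 that did not pass in edgeR (adjusted p = 1.00). Of 11916 genes tested for such a difference, edgeR called 0, with 261 at an unadjusted p under 0.05. It called 7 without control replicate 1, 6 without AA-rich replicate 1 and 6 without AA-rich replicate 2.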

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

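The tests of gene lists between stem-like and enterocyte-like cells, and the tests of explanations for the cholesterol and PPAR patterns, were chosen after the results were seen.

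The diet effect on 3 gene lists differed between stem-like and enterocyte-like cells of the same samples in camera's test of the interaction. For cholesterol synthesis the median over genes of the stem-like minus the enterocyte-like effect was 0.57 (class medians 0.04 and -0.54, adjusted p = 2.1e-16, and adjusted p = 0.476 with an estimated correlation). Most of the enterocyte-like fall came from AA-rich replicate 2. For PPAR targets and fatty acid oxidation this median of differences was -0.26 (class medians 0.05 and 0.30, adjusted p = 9.64e-10, and adjusted p = 0.662 with an estimated correlation). For immediate early and heat shock genes it was -0.37 (class medians -0.17 and 0.33, adjusted p = 3.19e-09, and adjusted p = 0.476 with an estimated correlation). The enterocyte-like call of this list was lost without AA-rich replicate 1 or control replicate 2. Its stem-like call was lost without control replicate 1, AA-rich replicate 1 or AA-rich replicate 2. Outside the epithelium, T or NK-like cells were 23.0% of the kept cells of AA-rich replicate 1, above both controls (10.6 and 12.4%), while AA-rich replicate 2 had 5.98% (exact permutation p = 1).

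Cholesterol synthesis genes were lower on the AA-rich diet in the epithelial-like cells. A changed mix of cell classes was argued against as the whole cause, since the median was below 0 within 5 of the 6 tested classes. It ran from -0.54 in enterocyte-like to -0.11 in tuft-like cells, with 0.04 in stem-like cells as the exception. The list did not pass in camera in enteroendocrine-like or tuft-like cells (adjusted p = 0.0632 and 0.122). All classes came from the same 4 samples, and a changed mix of clusters within cycling cells was not tested. AA-rich replicate 2 alone was argued against as the whole cause over all epithelial-like cells, since the median was -0.12 without it, with 21 of 25 genes lower, although the enterocyte-like call was lost. Unequal depth was not settled by its test, although the order of depth did not follow the diet. The pairs of samples closest in depth both gave medians below 0, at -0.079 (AA-rich replicate 1) and -0.45 (AA-rich replicate 2). However, the first was close to 0, and only 13 of 25 genes were lower in both pairs. An effect of the diet may also account for it, and that was not tested apart from differences between animals.

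PPAR targets and genes of fatty acid oxidation were higher on the AA-rich diet in enterocyte-like cells. A changed mix of enterocyte-like clusters was argued against by the largest cluster alone, with a median of 0.31 and 23 of 27 genes higher. The other clusters pooled gave the smaller median, 0.26, with 26 of 28 higher, but their own mix was not held fixed. In the controls the cluster led by Sult6b2 held 263 and 342 cells, and that led by Adh6a held 266 and 258. In the AA-rich samples they held 243 and 255 cells, and 106 and 167. Unequal depth was argued against, with medians of 0.26 and 0.45 in the pairs of samples closest in depth and 20 of 28 genes higher in both. A shift towards proximal intestine cannot be told apart, since proximal minus distal genes came to -0.29 in enterocyte-like cells, with a spread of 0.24, but 2 of 5 proximal genes were higher and distal genes were lower in the 5 other classes. No Hoxb gene was among the distal genes tested in enterocyte-like cells. Reads shared between close paralogs such as Acot1 and Acot2, an effect of the diet and differences between animals stayed open and were not tested.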

How the results depend on the processing

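With 2 samples per diet, leaving out a sample moved more results than any other choice, and the cause was not tested. A lone sample was then assumed to vary like the other diet's pair. RLE scaling, thinning to the lowest depth and the added fits within single stem-like and enterocyte-like clusters moved no count of genes or lists by over 1.5 times. Across all settings 56 counts of changed genes stayed within 1.5 times of the main count and 39 did not, and 65 share differences kept their sign and 5 did not. Thinning, Leiden resolution 0.5 and every deposited barcode were not run for single genes. Of 153 named-gene results, 110 kept their direction in each of the other settings that tested them, and 78 values passed in a setting where the main value did not. Paneth-like cells were too few for any test of genes. In simulated data 26 of 100 changes of 1 on the log2 scale were recovered in tuft-like cells and 95 in stem-like cells. Those genes were drawn independently, while real samples of the same number deviated together (correlation 0.197 in stem-like cells). A count of 0 calls therefore does not exclude changes of this size.

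DESeq2 called 5 genes in all epithelial-like cells, 1 in cycling, 1 in enterocyte-like, 1 in goblet-like, 2 in enteroendocrine-like and 2 in tuft-like cells. Without a filter on low counts, edgeR called 193 in stem-like, 236 in cycling, 104 in enterocyte-like, 104 in enteroendocrine-like and 51 in tuft-like cells, and 11 for the interaction. Of the named-gene results, 24 passed without that filter and not in the main test. Among them were Me1 (adjusted p = 1.8e-09), Hmgcs2 (2.0e-07), Angptl4 (2.7e-06), S100g (8.4e-05) and Gsdmc4 (0.0057) in enterocyte-like cells. The smallest there was that of Hspa1a (1.9e-39), whose log2 fold change ranged from -3.88 to 6.57 with a sample left out. A small p without the filter therefore did not mean that the samples of a diet were alike. A mitochondrial limit of 10% gave 0 in enteroendocrine-like cells. Leiden resolution 0.5 gave 1 in enterocyte-like cells and 3 for the interaction. With the estimated correlation 0 lists passed in all epithelial-like (7 in the main test), stem-like (3) and enterocyte-like cells (7), and with fry 0 in each.

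With the replicate number as a block, the counts were 6 in all epithelial-like, 134 in stem-like, 43 in enterocyte-like, 6 in goblet-like, 128 in enteroendocrine-like, 44 in tuft-like and 10 in T or NK-like cells, and 0 in cycling cells as without it. Samples of the same number deviated together, with correlations from 0.0964 (tuft-like) to 0.343 (all epithelial-like), and the deposited names of the control and the AA-rich sample of a number share a code. By chi-square per degree of freedom over all kept cells, the samples numbered 1 were the closest of the pairs compared (17.8). Those numbered 2 were the farthest apart of these pairs (148), against 67.4 and 134 within the diets. Control replicate 1 with AA-rich replicate 2, and control replicate 2 with AA-rich replicate 1, were not compared. No label says what a number or code marks, and 2 pairs cannot settle it. The block also turned Fads1 in stem-like cells to -0.00063 and Fads2 in enterocyte-like cells to -0.0289. Of the named-gene results, 20 passed in edgeR with the block and not in the main test. In stem-like cells these were Fos (adjusted p = 0.00073), Selenop (0.0011), Naaladl1 (0.00074), Bex1 (0.00038), Banp (0.0011), Cd74 (0.0014) and Fosb (0.0034). In enterocyte-like cells they were Me1 (0.00051), Hmgcs2 (0.0019), Angptl4, S100g, Gsdmc4, Pdk4, Mvk, Acot1, Cyp4a10 and Hspa1a. The others were Gcg in all epithelial-like (0.0239), Ang4 in goblet-like (0.0141) and Lgr5 in enteroendocrine-like cells (0.66, 0.0378).

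With each sample left out in turn, the counts ranged from 0 to 50 in all epithelial-like, 0 to 249 in stem-like, 0 to 375 in cycling, 0 to 66 in enterocyte-like, 1 to 366 in goblet-like, 17 to 264 in enteroendocrine-like and 0 to 295 in tuft-like cells, and from 0 to 7 for the interaction. The highest count came without AA-rich replicate 1 in every class, and without control replicate 1 for the interaction. Lists passing ranged from 3 to 8 in stem-like and 6 to 11 in enterocyte-like cells. The share differences ranged from -3.76 to 7.98 points for stem-like, -14.5 to 3.72 for enterocyte-like and -0.30 to 0.79 for tuft-like cells, and with every deposited barcode the Paneth-like difference was -0.19.

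Log2 fold changes that changed sign with a sample left out ranged, in all epithelial-like cells, from -0.0344 to 0.53 for Ascl2, -0.0777 to 0.56 for Olfm4, -0.13 to 0.34 for Ptger4, -0.11 to 0.15 for Fads2, -0.44 to 0.0324 for Cd74 and -0.42 to 0.13 for H2-Ab1. In stem-like cells they ranged from -0.20 to 0.0444 for Lgr5, -0.31 to 0.20 for Ascl2, -0.22 to 0.17 for Clu, -0.0382 to 0.58 for Ptger4, -0.0448 to 0.0484 for Fads1, -0.0735 to 0.0292 for Fads2 and -0.0203 to 0.41 for Hmgcs2. In enterocyte-like cells they ranged from -0.34 to 1.48 for Per1, -0.0388 to 0.26 for Ppargc1a -3.88 to 6.57 for Hspa1a, -0.48 to 1.05 for Olfm4, -0.71 to 0.50 for Ptger4, -0.76 to 0.36 for Fads1, -0.45 to 0.40 for Fads2 and -0.17 to 0.71 for Mki67. In cycling cells the ranges were -0.0802 to 0.21 for Ascl2, -0.58 to 0.35 for Ly6a, -0.13 to 0.0727 for Ptger4, -0.0342 to 0.0955 for Fads1, -0.72 to 2.29 for Pdk4 and -0.23 to 0.0351 for Mki67. In goblet-like cells the ranges were -0.25 to 0.42 for Ascl2, -0.21 to 0.17 for Ptger4, -0.0643 to 0.11 for Fads1, -0.0145 to 0.0722 for Fads2, -1.28 to 0.99 for Pdk4 and -0.0191 to 0.38 for Mki67. In tuft-like cells the ranges were -0.016 to 0.18 for Lgr5, -0.50 to 0.0869 for Ascl2, -0.17 to 0.40 for Olfm4, -1.52 to 0.65 for Ptger4, -0.39 to 0.19 for Fads2, -0.18 to 0.74 for Hmgcs2 and -0.25 to 0.67 for Mki67, and in enteroendocrine-like cells -0.0679 to 0.51 for Mki67. With doublets kept, Ascl2 in stem-like cells was at 0.00084, Itga2 in enterocyte-like cells at 0.0432, and Ptger4 in tuft-like cells at 0.29. Without a filter on low counts, Fads2 in enterocyte-like cells was at -0.0019. With the mitochondrial limit of 10%, Fads1 and Fads2 in stem-like cells were at -0.0155 and 0.0255, Aurka, Ptger4, Fads2 and Mki67 in enterocyte-like cells at -0.0466, 0.12, -0.0418 and -0.27, Fads1 in cycling cells at -0.0491 and Ptger4 in goblet-like cells at 0.0071.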

Other observations

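The gene list tests in T or NK-like cells and within each epithelial-like class, the lists of proximal and distal genes and all but the Paneth cell test of Defa24 were chosen after results were seen. Genes named in the next 3 paragraphs were chosen after their values were seen.

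T or NK-like cells, the lymphocytes of the crypt samples, showed lower levels of cholesterol synthesis genes on the AA-rich diet, as epithelial-like cells did. Of 23 genes, 22 were lower (median -0.54) and 15 had both AA-rich samples on the same side of both controls, where chance gives a share of 0.333. Ldlr stood at 95.4 and 88.3 CPM in the controls and at 46.4 and 37.7 in the AA-rich samples (-1.08 ± 0.19), Hmgcs1 had -0.89 ± 0.18 and Msmo1 -0.93 ± 0.21. The list fell in camera (adjusted p = 1.19e-14, and adjusted p = 0.609 with an estimated correlation). Immediate early and heat shock genes were higher in 13 of 17 (median 0.51, 0.00105), cell cycle genes in 17 of 21 (median 0.31, 0.00836) and prostaglandin receptors and cAMP-CREB targets in 11 of 12 (median 0.34, 0.00836), while fatty acid synthesis genes were lower in 9 of 10 (median -0.24, 0.0107), all with adjusted p = 0.609 with an estimated correlation. Interferon-stimulated genes were lower in 14 of 19 (median -0.14, adjusted p = 0.00836, and adjusted p = 0.651 with an estimated correlation). The immediate early levels were highest in AA-rich replicate 1 (sums 4224, 3592, 6438 and 3606 CPM) and the cell cycle levels in AA-rich replicate 2 (648, 594, 651 and 921). Of 8641 genes tested, edgeR called 0, with 306 at an unadjusted p under 0.05, and DESeq2 called 0.

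Lgr5 stem cell genes were higher on the AA-rich diet within 3 of the 6 tested classes, in 22 of 22 in cycling cells (median 0.18, camera adjusted p = 8.48e-08), 20 of 22 in goblet-like cells (0.17, 0.000211) and 19 of 22 in enteroendocrine-like cells (0.27, 1.88e-08). With an estimated correlation the adjusted p was 0.445, 0.916 and 0.427. The 2 clusters of cycling cells were mixed differently by diet, with 1 of them at 45.2 and 43.0% of the class in the controls and 54.3 and 49.5% in the AA-rich samples, and the lists were not tested within them. The list did not pass in tuft-like cells (14 of 20 higher, median 0.06, 0.368) or enterocyte-like cells (9 of 18 higher, median -0.02, 0.498), and in stem-like cells 13 of 22 were lower (median -0.07, 0.293). Where the list rose, enterocyte nutrient uptake genes were lower, in 19 of 21 in enteroendocrine-like (-0.29, 2.14e-08), 17 of 21 in cycling (-0.11, 0.0221) and 17 of 20 in goblet-like cells (-0.12, 0.0272), with adjusted p = 0.843, 0.665 and 0.916 with an estimated correlation. In enteroendocrine-like cells 11 of 12 enterocyte markers were lower, 4 of them passing in edgeR adjusted over the list alone and 0 over all genes. Cholesterol synthesis genes were lower in 24 of 25 in cycling cells (-0.23, 8.99e-08) and 25 of 25 in goblet-like cells (-0.23, 2.68e-09), with adjusted p = 0.445 and 0.916 with an estimated correlation.

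Genes that mark the distal small intestine were lower in stem-like cells of the AA-rich diet in 7 of 8 (median -0.82), with Hoxb6 at -1.78 ± 0.52, Hoxb8 at -1.52 ± 0.42, Hoxb9 at -1.44 ± 0.46 and Hoxb7 at -1.13 ± 0.33, all at or below 7.20 CPM in each sample. They were lower in 7 of 7 in cycling cells (-0.70), 6 of 6 in goblet-like cells (-0.41), 7 of 7 in enteroendocrine-like cells (-0.49) and 3 of 4 in tuft-like cells (-0.31), and higher in 5 of 5 in enterocyte-like cells (0.20). No Hoxb gene was tested in tuft-like or enterocyte-like cells, so the directions compare partly different genes. Those tested in enterocyte-like cells were Fgf15, Slc51b, Fabp6, Osr2 and Slc51a. Camera gave p = 8.55e-07 in stem-like and 1.0e-06 in cycling cells, and p = 0.0542 and 0.0417 with an estimated correlation. Over all epithelial-like cells 7 of 10 were lower (median -0.26), while the ileal genes Fabp6 (0.69 ± 0.53), Fgf15 (0.49 ± 0.42) and Slc10a2 (0.13 ± 0.34) were higher. Fabp6 stood at 315, 159, 193 and 574 CPM and Fgf15 at 3.44, 2.63, 2.44 and 6.05, both highest in AA-rich replicate 2. Fabp6 was higher in stem-like (0.42) and enterocyte-like cells (0.94). It was lower in cycling (-0.70), goblet-like (-0.46), enteroendocrine-like (-0.18) and tuft-like cells (-2.82 ± 0.38, edgeR adjusted p = 0.135). The labels do not say whether the same stretch of intestine was taken from every mouse, so these values and that of Gcg below were not told apart from a difference in the stretch sampled. An unnamed cluster led by Fabp6, with Fgf15 and Slc10a2 among its top 10 genes, held 6.54, 3.20, 3.10 and 4.23% of epithelial-like cells in control replicates 1 and 2 and AA-rich replicates 1 and 2. The peptide transporter gene Slc15a2 stood at 15.8, 8.34, 0 and 2.02 CPM in stem-like cells, and Gcg at 1167, 1567, 543 and 651 CPM in enteroendocrine-like cells (-1.19 ± 0.22, edgeR adjusted p = 0.717). Xist stood at 712, 668, 758 and 1021 CPM over all epithelial-like cells (0.37 ± 0.19), and the other sex-linked genes were too low to be tested.

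Defa24 was higher on the AA-rich diet in tuft-like and enteroendocrine-like cells. RNA from Paneth cells met a test bound of 3 times in all 4 samples. The ratio of Defa24 to Lyz1 UMIs in these classes lay at 0.351, 0.498, 0.668 and 0.657 of that in the same sample's Paneth-like cells. Each was below 1 by more than its counting interval (upper bounds 0.431, 0.619, 0.741 and 0.756), and the interval of control replicate 1 reached down to 0.285. RNA with the make-up of the Paneth-like cells was thus not matched exactly, and so wide a bound cannot settle it. Free RNA at a like level in every class was argued against as the whole cause, as the level was at least 1.81 times that in T or NK-like cells in each sample. Without the 5 richest tuft-like and the 5 richest enteroendocrine-like cells of each sample this ratio lay from 0.716 to 1.08. It lay from 1.04 to 1.25 with the 5 richest T or NK-like cells also left out. Leaving out the rich cells took the lower AA-rich level over the higher control level from 4.28 to 1.56, so they may account for much of the difference. Without them both AA-rich samples stayed above both controls in enteroendocrine-like cells. A CPM ratio near 1 does not show free RNA, because T or NK-like cells held far fewer UMIs per cell. Outside the 5 richest of 140 and 269 cells, enteroendocrine-like cells of AA-rich replicates 1 and 2 held 119 and 451 Defa24 UMIs. All 1197 and 509 T or NK-like cells held 50 and 99, which argues against free RNA in like UMI numbers per cell as the whole cause there. Whether the few rich cells are doublets with Paneth cells or cells that make Defa24 themselves stayed open. The difference was not particular to these 2 classes. In goblet-like cells Defa24 stood at 241 and 375 CPM in the controls and at 432 and 885 in the AA-rich samples, without passing in edgeR. Without the 5 richest goblet-like cells of each sample it stood at 183 and 263 against 289 and 716. The Defa24 to Lyz1 UMI ratio in Paneth-like cells was 1.64 and 2.00 in the controls and 2.56 and 6.78 in the AA-rich samples.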
